A study of Homo sapiens with 6 samples.

How the data were processed

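RNA of MOLM-14 cells was measured on Affymetrix U133 Plus 2.0 arrays, 3 after DMSO and 3 after 25 nM cortistatin A (CA), each for 3 h. Cells were plated in triplicate at 500000 to 800000 cells per mL, and labelled RNA was made from 100 ng of total RNA with an Affymetrix kit that primes at the 3' end, per the labels' protocols. RNA was isolated with either of 2 reagents, and which of them served which sample is not given in the sources used here. The authors deposited 1 table of log2 expression values per probe set, made with RMA and the affy package per the submitters' processing notes. RMA corrects background, quantile normalises the arrays and summarises the probes of a probe set on the log2 scale, so a change shared by all genes would be lost and differences of dim genes can be compressed. Package versions and the probe annotation used are not given in the sources used here, and neither are scan dates or batches. The values were used as deposited, with no further background correction, scaling or filter on dim probe sets.

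The table held 54675 probe sets, of which 62 were Affymetrix controls and were left out. Of the other 54613, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none. Only those with 1 symbol were named. Of these, 41037 were matched by gene number to a gene table of assembly GRCh38.p14, and 0 symbols needed an update. For each of 19775 genes the probe set with the highest mean log2 value over all 6 arrays was used; 10523 genes had more than 1. The gene table also gave which genes are neighbours, and no positions are reported because the files name no genome build.

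Groups came from the sample titles. CA was compared with DMSO with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, no block), two-sided, with Benjamini-Hochberg adjustment over all genes, and a gene was called changed at an adjusted p under 0.05. With 3 against 3 samples, an exact permutation test of 1 gene cannot give a two-sided p below 0.1. The p-values rest instead on limma's model, which combines the spread of each gene with a spread pooled over genes. The prior had 2.53 degrees of freedom. Over all genes the median SE of the log2 change was 0.07, the median SD was 0.07 in DMSO and 0.09 in CA, and the median log2 change was 0.0037. The same fit was run on all non-control probe sets. Folds are 2 to the power of the log2 change, with 95% confidence intervals from limma. The 62 control probe sets were tested apart, and 0 passed in limma, with 1 at an unadjusted p under 0.05.

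The 22 gene lists, the design and the rule for named genes were fixed before the data were examined. The lists were 4 factors recalled from the study (CEBPA, IRF8, IRF1, ETV6), haematopoietic transcription factors, monocyte and macrophage markers, neutrophil granule and granulocyte genes, MLL fusion targets and leukaemia stem cell genes, interferon stimulated genes, immediate early and MAPK feedback genes, NF-kB and inflammatory genes, Mediator subunits, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, G1/S and DNA replication, G2/M and mitosis, p53 targets, sterol and fatty acid synthesis, hypoxia response, TGF-beta, Notch and Wnt targets, unfolded protein and heat shock genes, apoptosis regulators, and markers of erythroid and megakaryocyte, of T, NK and B, and of epithelial and fibroblast cells. Of the members, 88 genes had no probe set with 1 symbol and were left out. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated per list. Camera compares a list with the other genes. Fry, run as an alternative, tests whether the genes of a list move on balance one way, and compares them with no other genes.

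Genes were named by rule: the 10 largest rises and the 10 largest falls among changed genes whose groups did not overlap, up to 4 changed members of each list with the smallest p, the 2 members with the smallest p of a list that passed without a changed member, and CDK8, CDK19, CCNC, MED12, MED13, CEBPA, IRF8, IRF1 and ETV6. This gave 55 genes, of which 46 were past the threshold. Genes named outside the rule are marked as chosen after their values were seen.

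The steps were tested on simulated data for the comparison of CA with DMSO over 19775 genes, 200 of them changed. Each gene had its real mean and a spread drawn at random from the distribution that limma fitted over all genes. The simulation held no correlation between genes, no differences between arrays and no link of spread to signal, so its rates may not hold for the real arrays. Of genes raised by a log2 change of 0.3, 0.5 and 1, 8.82%, 55.9% and 97.0% were called, and of those lowered by the same sizes 6.06%, 54.5% and 90.9%. Of the 109 genes called, 5 were unchanged ones, and with no gene changed limma called 0. In this simulation, small changes were mostly missed.

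The alternatives were the replicate number as a block, eBayes with an intensity trend and robust fit, no dim probe sets, quantile normalisation again, arrays shifted to the same median, array weights, the mean over the probe sets of a gene, no probe sets of the types _x_at, _s_at and _a_at, which can match several transcripts, a change of at least 1.2-fold, an adjusted p under 0.01, other list tests, and each array left out in turn with the probe sets kept.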

Results

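Gene expression was measured in MOLM-14, an established human acute myeloid leukaemia cell line that carries the MLL-AF9 fusion. Cells were exposed for 3 h to 25 nM cortistatin A (CA), a steroidal alkaloid that inhibits the Mediator kinases CDK8 and CDK19, or to the solvent dimethyl sulfoxide (DMSO). Each group had 3 samples, and each sample was hybridised to 1 Affymetrix U133 Plus 2.0 array. The comparison asks which transcripts differed after 3 h of CA. Median log2 values of the arrays lay between 5.03 and 5.08, and correlations between arrays lay between 0.996 and 0.998. The number of arrays limits the precision. The labels describe wells plated in triplicate and name no separate cultures or days, so the p-values measure the spread between these samples, which may be technical.

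ALDH1A3, which encodes a retinaldehyde dehydrogenase, had the largest rise at the probe sets used. Its log2 value was 7.40 ± 0.10 in DMSO and 9.02 ± 0.08 in CA (mean ± SD, n = 3 each), which is 3.08-fold higher (95% confidence interval 2.75 to 3.45). BHLHE40, a transcriptional repressor, rose 2.26-fold (2.04 to 2.50), the oxysterol receptor GPR183 rose 2.25-fold (2.02 to 2.51), and the cytokine TNF rose 2.25-fold (2.01 to 2.51). The falls were smaller. CCNE2, which encodes cyclin E2, fell by 30.0%, from a log2 value of 10.60 ± 0.04 to 10.08 ± 0.11, and the linker histone gene H1-10 fell by 29.5%.

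Of 19775 genes, 177 had an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). Of these, 166 were higher in CA and 11 were lower, so that 93.8% of the changed genes had risen. The number depends on the fit: it was 74 without the _x_at, _s_at and _a_at probe sets, 351 without dim probe sets, and 546 (450 higher, 96 lower, 82.4% higher) with an intensity trend and a robust fit. With the replicate number as a block, a pairing that the labels do not state, it was 6, all higher. At an adjusted p under 0.01 it was 25, all higher. Among the 166 risen genes the rises ranged from 1.22-fold to 3.08-fold with a median of 1.38-fold. Of the risen genes, 9 were at least 2-fold higher and 52 were at least 1.5-fold higher. The falls ranged from 19.3% to 30.0%. In all 177 genes the 3 CA values lay on one side of the 3 DMSO values; over all genes this held for 3821, or 19.3%, where chance gives 10%. At an unadjusted p under 0.05 there were 1403 genes higher and 889 lower. The number of calls rested on all 6 arrays: it was 5 without DMSO replicate 1, 8 without DMSO replicate 2, 1 without DMSO replicate 3, 6 without CA replicate 1, 9 without CA replicate 2 and 112 without CA replicate 3. The 177 genes kept their direction in each of these 6 fits, which was certain, since their groups do not overlap and each fit reused all arrays but 1. Their changes were between 0.868 and 1.16 times those from all arrays. Of the 55 genes named by rule, 5, 6, 1, 5, 7 and 31 passed in these fits in the same order, and ALDH1A3 passed in each.

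**Figure D1:**
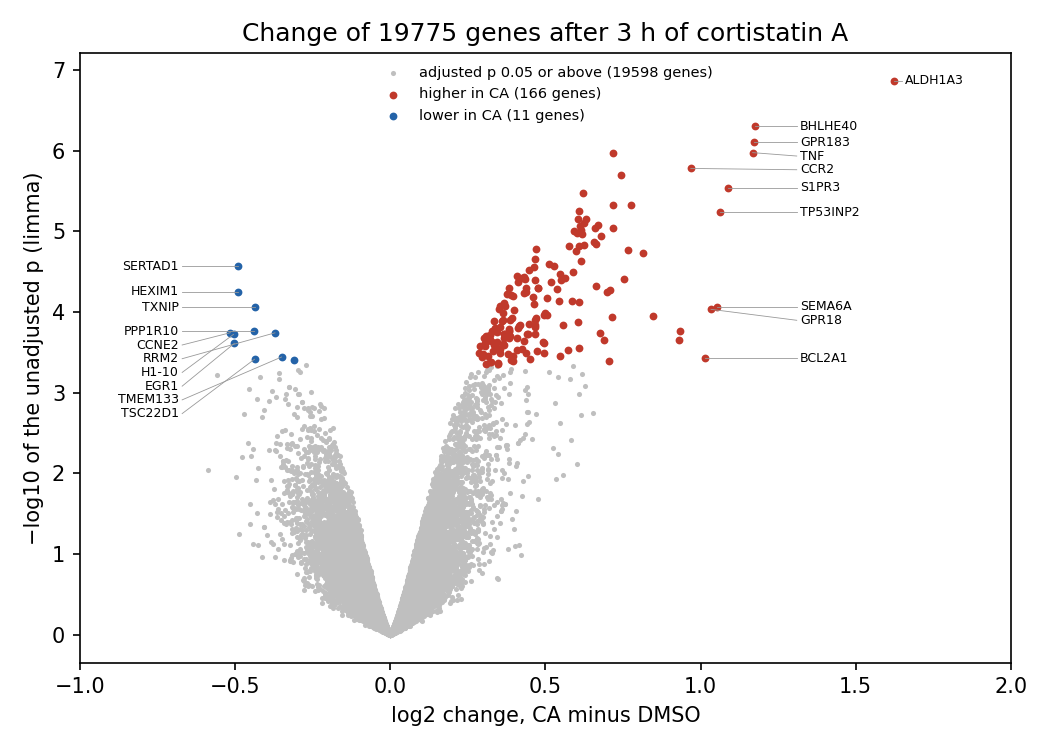
Each point is 1 of 19775 genes, with the log2 change (CA minus DMSO, 3 arrays each) on the horizontal axis and −log10 of the unadjusted limma p on the vertical axis; red marks the 166 genes higher in CA and blue the 11 lower at an adjusted p under 0.05. The 10 largest rises and the 10 largest falls are named, and ALDH1A3 lies farthest to the right.

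S1PR3, a receptor for sphingosine 1-phosphate, rose 2.13-fold (adjusted p = 0.00706), and GPR18 rose 2.05-fold (adjusted p = 0.0229). The chemokine receptor gene CCR2 rose 1.96-fold (adjusted p = 0.00546), although part of its sequence is close to that of other chemokine receptors and its second probe set gave a log2 change of 0.25. TP53INP2, which takes part in autophagy, rose 2.09-fold (adjusted p = 0.00877). SEMA6A, a transmembrane semaphorin, rose 2.07-fold (adjusted p = 0.0219). BCL2A1, an anti-apoptotic relative of BCL2, rose 2.02-fold (95% confidence interval 1.57 to 2.60, adjusted p = 0.0446). Other probe sets gave smaller values for some of these genes. The log2 change was 0.09 at the second probe set of ALDH1A3, 0.35 at that of BHLHE40 and -0.14 at that of S1PR3. It was -0.083, 0.078, 0.59 and 0.60 at the other probe sets of SEMA6A, against 1.05 at the one used.

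The other large falls were each under 30.0%. EGR1, an early response transcription factor, fell by 29.4% (adjusted p = 0.0343). HEXIM1, which inhibits the elongation factor P-TEFb, fell by 28.9% (adjusted p = 0.0178). SERTAD1 fell by 28.8% (adjusted p = 0.0136), and PPP1R10, a nuclear regulator of protein phosphatase 1, fell by 26.2% (adjusted p = 0.0307). TXNIP, the thioredoxin-interacting protein, fell by 26.0% (adjusted p = 0.0221), and TSC22D1 fell by 26.1% (adjusted p = 0.0454). RRM2, a subunit of ribonucleotide reductase, fell by 22.7% (adjusted p = 0.0307), and TMEM133 fell by 21.5% (adjusted p = 0.0434). TMEM133 was dim, with mean log2 values of 4.04 in DMSO and 3.69 in CA, below the array medians. Probe sets of one gene differed here too. For CCNE2 the log2 change was -0.51 at the probe set used and -0.21 at the other (adjusted p = 0.624), and for RRM2 it was -0.37 and -0.21 (adjusted p = 0.327). Log2 changes at the other probe sets were -0.05 and -0.09 for EGR1, -0.63 and -0.13 for HEXIM1, and -0.06, -0.09 and 0.00 for TSC22D1.

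**Figure D2:**
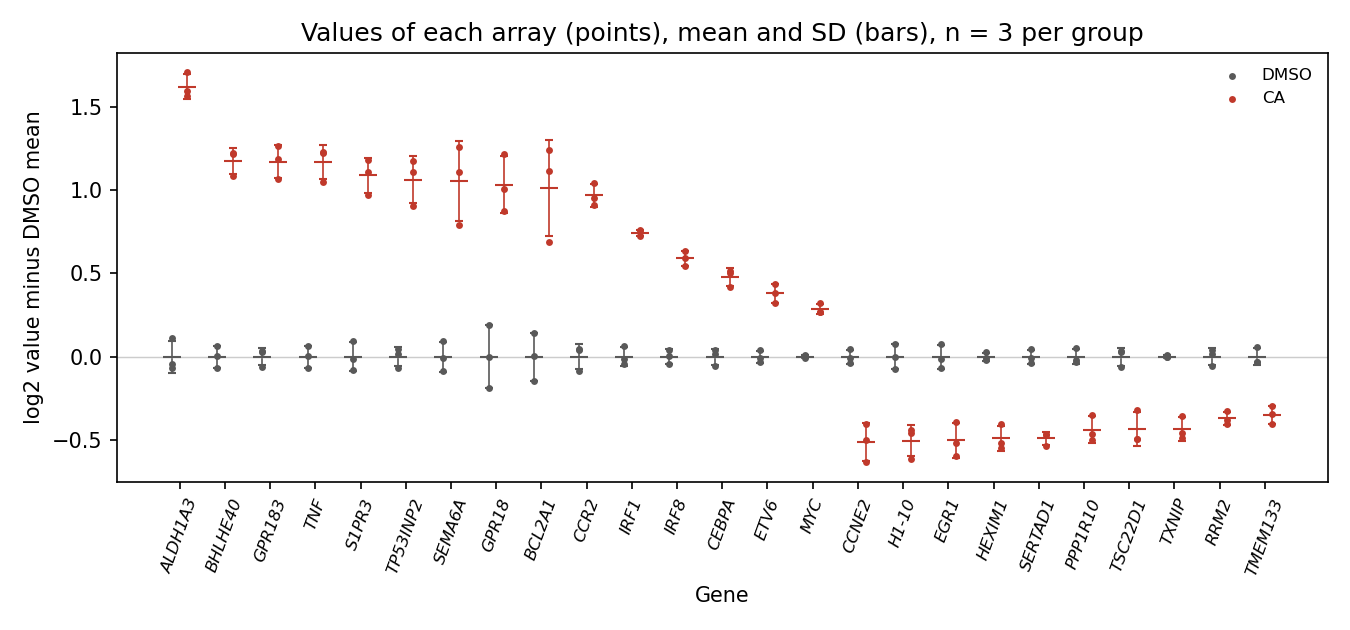
Log2 values of each array (points) minus the DMSO mean of each gene, with the group mean and SD as bars (n = 3 each; grey DMSO, red CA), for the 10 largest rises, for IRF1, IRF8, CEBPA, ETV6 and MYC, and for the 10 largest falls. The CA values of each gene shown lie on one side of its DMSO values.

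Transcripts of the kinases that CA inhibits differed by less than the test could resolve. CDK8 was 0.908-fold its DMSO level (95% confidence interval 0.813 to 1.01, adjusted p = 0.488), and CDK19 was 0.988-fold (0.922 to 1.06, adjusted p = 0.914). CCNC, which encodes their partner cyclin C, had a log2 change of 0.0061 (-0.097 to 0.11, adjusted p = 0.972). MED12 and MED13, the other components of the kinase module, had log2 changes of 0.09 and -0.16 (adjusted p = 0.704 and 0.457). None of the 31 measured Mediator subunits passed in limma, over all genes or adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05. As a list they had an adjusted p of 0.995 in limma's camera test, with a median log2 change of 0.01, a mean of -0.0027 and a downward test direction.

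Several transcription factors of blood cells rose. CEBPA, a regulator of granulocyte and monocyte formation, rose 1.39-fold (95% confidence interval 1.28 to 1.52). IRF8, a regulator of monocyte formation, rose 1.51-fold (1.39 to 1.63), IRF1 rose 1.68-fold (1.55 to 1.81) and ETV6 rose by 0.38 on the log2 scale (0.26 to 0.50). These 4 genes were listed because the study is recalled to name them as responding, so their joint rise, with all 4 passing both over all genes and adjusted over the list alone, is not independent evidence of direction (camera adjusted p = 1.19e-09, 0.0330 with an estimated correlation). A separate list of haematopoietic transcription factors had 49 measured members. Of these, 8 rose and none fell over all genes, among them BHLHE40, HLX at 1.53-fold, LMO2 at 1.43-fold and ETS2 at 1.44-fold; adjusted over the list alone 19 rose and none fell. Its median log2 change was 0.12 (camera adjusted p = 1.36e-09), and the call was lost with adjusted p = 0.0664 with an estimated correlation. In limma's unadjusted test, 21 members were higher and 0 were lower.

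Genes that MLL fusion proteins activate, or that mark leukaemia stem cells, had the largest median shift among the lists with more than 4 members. The list had 35 members, of which 8 were not analysed here, all of them HOXA genes, so the shift leaves out these well-known MLL fusion targets. Of the 27 measured members 7 rose and 0 fell over all genes, and 15 rose and 0 fell adjusted over the list alone. FUT4, a fucosyltransferase, rose 1.51-fold, and the transcription factor genes MYB, PBX3 and MEF2C rose 1.29-fold, 1.29-fold and 1.28-fold. The median log2 change was 0.22 (camera adjusted p = 3.33e-10, 0.0330 with an estimated correlation). At an unadjusted limma p under 0.05, 17 were higher and 0 lower. This list shares 5 measured members with the haematopoietic transcription factors, among them MYB and MEF2C.

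Markers of monocytes and macrophages were higher as a list. Of 48 measured members, CCR2 and MS4A7, a membrane protein of macrophages that rose 1.47-fold, passed over all genes, and 9 rose and 0 fell adjusted over the list alone. Without an adjustment, limma had 11 higher and 1 lower. The median log2 change was 0.09 (camera adjusted p = 3.62e-05, 0.0400 with an estimated correlation). Of 30 measured genes of neutrophil granules and granulocytes, FUT4 was the one that rose, over all genes and adjusted over the list alone. This list did not pass camera (adjusted p = 0.235), but passed without dim probe sets (adjusted p = 0.0297).

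Markers of other cell types gave no calls in limma. Over all genes and adjusted over the list alone, 0 of 17 erythroid and megakaryocyte markers, 0 of 27 markers of T, NK and B cells and 0 of 20 epithelial and fibroblast markers passed. At an unadjusted p under 0.05 the numbers higher were 2, 3 and 1, and the numbers lower were 0, 2 and 0. Camera adjusted p-values were 0.536, 0.995 and 0.780.

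**Figure D3:**
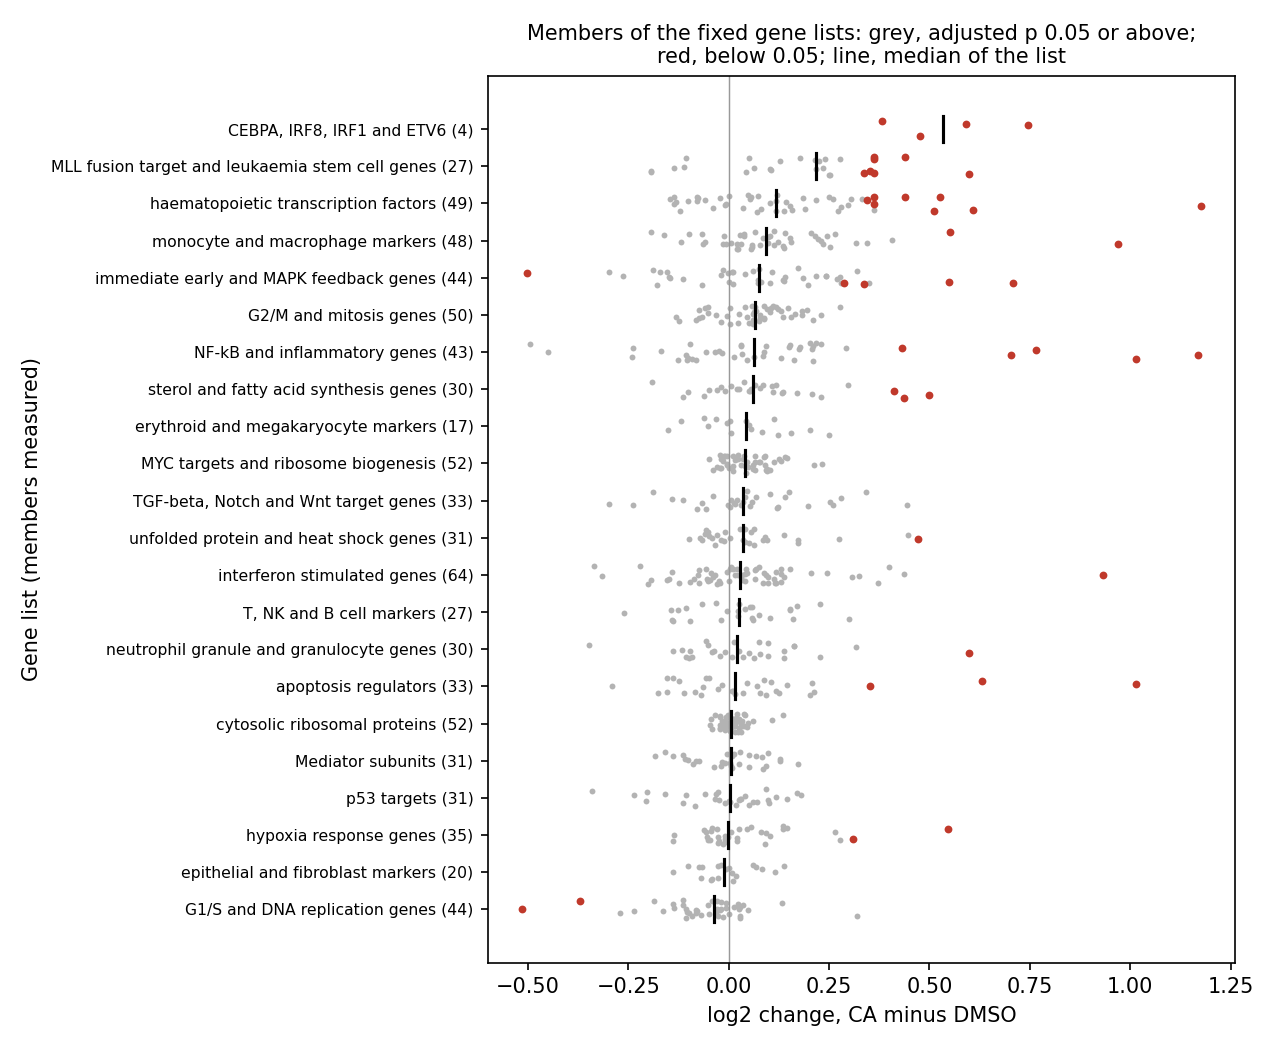
Log2 changes (CA minus DMSO) of the measured members of the 22 gene lists, with the number of measured members after each name. The MLL fusion target list has a median of 0.22 and the G1/S and DNA replication list a median of -0.04.

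Inflammatory genes rose in part. Of 43 measured NF-kB and inflammatory genes, TNF, LTB, TNFAIP3, BCL2A1 and CCR7 rose and 0 fell over all genes, and adjusted over the list alone 12 rose and 2 fell. TNFAIP3, an inhibitor of NF-kB signalling, rose 1.35-fold. The lymphotoxin gene LTB rose 1.70-fold at the probe set used, while its other probe set gave a log2 change of -0.011. CCR7, named after its values were seen, rose 1.63-fold, from a mean log2 value of 4.56, below the array medians, to 5.26. The list passed camera (adjusted p = 0.00380) but had adjusted p = 0.132 with an estimated correlation. At an unadjusted limma p under 0.05, 14 were higher and 5 lower. Of 64 interferon stimulated genes, the chemokine gene CXCL10 rose 1.91-fold (95% confidence interval 1.54 to 2.36) and passed over all genes, and 3 rose adjusted over the list alone (camera adjusted p = 0.221).

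Immediate early genes and feedback regulators of MAPK signalling went both ways. Of 44 measured members, 4 rose and EGR1 fell over all genes, and 11 rose and 2 fell adjusted over the list alone. FOSL2, a member of the AP-1 family, rose 1.63-fold, ETV5 rose 1.26-fold, and MYC rose 1.22-fold (95% confidence interval 1.14 to 1.31). DUSP6, a phosphatase of ERK, rose 1.46-fold and was named after its values were seen. At an unadjusted limma p under 0.05, 14 were higher and 4 lower. The other probe sets of ETV5 gave log2 changes between 0.04 and 0.24. The median log2 change of the list was 0.08 (camera adjusted p = 0.00442), with adjusted p = 0.254 with an estimated correlation.

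Cell cycle genes were tested as 2 lists. Of 44 measured G1/S and DNA replication genes, CCNE2 and RRM2 fell, each with a smaller change at its other probe set, and 0 rose over all genes; adjusted over the list alone 1 rose and 4 fell. At an unadjusted limma p under 0.05, 2 were higher and 10 lower. The median log2 change was -0.04 (camera adjusted p = 0.000217), with adjusted p = 0.136 with an estimated correlation. Of 50 G2/M and mitosis genes none passed in limma over all genes, 3 rose adjusted over the list alone, and 13 were higher and 0 lower without an adjustment. CENPE and CENPF, which encode centromere proteins, had log2 changes of 0.28 and 0.23 (adjusted p = 0.0940 and 0.0839). This list was shifted upward in camera (median 0.06, adjusted p = 8.34e-05), with adjusted p = 0.266 with an estimated correlation. Whether the 2 lists differed from each other was not tested.

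Genes of growth and translation gave no calls for single genes. Of 52 MYC targets and genes of ribosome biogenesis, 0 passed in limma over all genes or adjusted over the list alone, and 6 were higher and 0 lower at an unadjusted p under 0.05. BYSL and NOP2, both needed to make ribosomes, had log2 changes of 0.21 and 0.23 (adjusted p = 0.144 and 0.161). The list had a median log2 change of 0.04 and a camera adjusted p of 0.00380, with adjusted p = 0.221 with an estimated correlation. Of 52 cytosolic ribosomal protein genes 0 passed in limma on either count, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.780). Of 31 p53 targets 0 passed in limma on either count, with 2 higher and 3 lower without an adjustment. Their median log2 change was 0.0030 and their mean was -0.013, with a downward test direction (camera adjusted p = 0.816).

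Genes of sterol and fatty acid synthesis included 3 that rose. Of 30 measured members, SQLE at 1.33-fold, MSMO1 at 1.35-fold and INSIG1 at 1.41-fold passed over all genes and 0 fell; adjusted over the list alone 4 rose and 0 fell. SQLE and MSMO1 encode enzymes of cholesterol synthesis, and INSIG1 encodes a protein that restrains it. At an unadjusted limma p under 0.05, 9 were higher and 1 lower. The median log2 change was 0.06 (camera adjusted p = 0.000449), with adjusted p = 0.119 with an estimated correlation.

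Apoptosis regulators included risen genes of both kinds. Of 33 measured members, BCL2L11, which promotes apoptosis, rose 1.55-fold, and BCL2 and BCL2A1, which oppose it, rose 1.28-fold and 2.02-fold. The other probe sets of BCL2 gave log2 changes of 0.25, 0.21 and -0.057, against 0.35 at the probe set used. Those of BCL2L11 gave 0.07 to 0.80, against 0.63. Adjusted over the list alone 5 rose, and the list had a camera adjusted p of 0.164, or 0.0316 without CA replicate 3. Of 35 hypoxia response genes, ADM at 1.46-fold and DDIT4 at 1.24-fold rose, and 3 rose adjusted over the list alone; the median log2 change was -0.0024, the mean was 0.05 and the test direction was upward (camera adjusted p = 0.214). Of 31 unfolded protein and heat shock genes, VLDLR, which encodes a lipoprotein receptor, rose 1.39-fold, and 4 rose adjusted over the list alone (camera adjusted p = 0.125, 0.0414 with array weights and 0.0187 without CA replicate 3). Of 33 targets of TGF-beta, Notch and Wnt signalling, 0 passed in limma over all genes, 2 rose adjusted over the list alone, and 6 were higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.330).

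Of the 22 lists, 10 passed camera, 9 upward and 1 downward, and 3 of them also passed with an estimated correlation: the 4 factors recalled from the study, the MLL fusion targets and the monocyte and macrophage markers. The array of CA replicate 3 stood apart from the rest. On the first principal component, which held 31.6% of the variance, it lay at 19.7 and the other arrays lay between -8.25 and 0.73. The second component, with 29.1% of the variance, had the DMSO arrays between -11.7 and -3.33 and the CA arrays between 1.70 and 13.0. Without CA replicate 3 there were 12 lists past the threshold, and without any other single array there were 10. DMSO replicates 1 and 3 with CA replicate 3 were also set against the other arrays, a split that mixed the groups. It put 10 lists past the camera threshold, of which 0 passed with an estimated correlation. The MLL fusion target, haematopoietic transcription factor, immediate early, G2/M and sterol lists passed camera both there and in the real split. In that split a response to CA would add to the spread within groups, so its 0 cannot be set against the 3 of the real split.

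The same fit over 54613 probe sets, with no choice of 1 probe set per gene, had 120 past the threshold, 116 higher and 4 lower. They included 87 named genes and 6 probe sets with no single gene symbol. This number fell to between 0 and 6 when 1 array was left out: it was 0 without DMSO replicate 1, DMSO replicate 3, CA replicate 1 or CA replicate 2, 1 without DMSO replicate 2 and 6 without CA replicate 3. Of the 177 changed genes, 117 had more than 1 probe set. Of their 247 other probe sets, 208 had a log2 change of the same sign, and 33 of these were past the threshold in this fit, with 0 past it in the opposite direction.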

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

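Of the fits in this part, 2 kinds were chosen only after the data were seen: leaving out each array with the intensity trend and robust fit, and the fit with each array's gap between dimmer and brighter genes as a covariate. Of 594 results for named genes under the planned and added alternatives that kept all arrays, 477 stayed on their side of the threshold, 474 of them with the same sign, 109 were no longer past it, 7 newly passed and 1 turned from a call to the opposite sign; with 1 array left out, 109 stayed, 106 of them with the same sign, and 221 were no longer past it. The call that turned was LTB, whose log2 change was -0.011 without probe sets of the _x_at, _s_at and _a_at types, because that setting moves it to another probe set. The other changes of sign were in genes that passed in neither fit: CCNC (0.0061 as reported) had -0.0045 after quantile normalisation again, -0.15 with the mean over probe sets, -0.0048 without DMSO replicate 1 and -0.0084 without CA replicate 2, MED12 (0.09 as reported) had -0.091 without the _x_at, _s_at and _a_at types, and CDK19 (-0.017 as reported) had 0.0013 without CA replicate 1. Among list results that stayed on their side of the threshold, the test direction differed in 13 with all arrays and in 11 with 1 array left out, all of them lists that passed in neither fit.

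Against 177 changed genes (166 higher, 11 lower) and 120 probe sets (116 higher, 4 lower), the intensity trend with a robust fit gave 546 genes (450 and 96) and 740 probe sets (640 and 100), and shared 175 genes with the 177. Without dim probe sets there were 351 genes (311 and 40) and 398 probe sets (365 and 33), with 173 shared. Array weights gave 245 genes (224 and 21) and 196 probe sets (185 and 11), with 177 shared. Without the _x_at, _s_at and _a_at probe sets there were 74 genes (72 and 2), with 73 shared and fewer genes tested. The mean over the probe sets of a gene gave 126 genes (118 and 8), with 114 shared; of the 46 named genes past the threshold 36 stayed past it, and the log2 change of ALDH1A3 was 0.85 (1.62 as reported). At an adjusted p under 0.01 limma gave 25 genes (25 and 0) and 5 probe sets (5 and 0), where 889 genes and 2024 probe sets were lower without an adjustment. The numbers lower were 19 genes and 10 probe sets after quantile normalisation again, and 6 genes and 2 probe sets with arrays shifted to the same median; the percent of changed genes that were higher was 89.3 and 96.1. It was 82.4 with the trend and 82.3 with the covariate, which gave 186 genes (153 and 33, 148 shared) and 72 probe sets (67 and 5). Apart from the filters, the cause of these shifts was not tested.

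Leaving out 1 array gave 1 to 112 genes (1 to 103 higher, 0 to 9 lower) and 0 to 6 probe sets (0 to 6 higher, 0 lower) in limma, with the fewest genes without DMSO replicate 3 and the most without CA replicate 3; fewer arrays also leave fewer degrees of freedom. Without an adjustment, 587 to 1276 genes and 1318 to 2856 probe sets were then lower. With the trend and robust fit the numbers were 317 genes without DMSO replicate 1 (284 higher, 33 lower), 355 without DMSO replicate 2 (324 and 31), 317 without DMSO replicate 3 (281 and 36), 368 without CA replicate 1 (308 and 60), 424 without CA replicate 2 (339 and 85) and 801 without CA replicate 3 (651 and 150). Lists past the threshold numbered 10 in camera, 3 with an estimated correlation, 14 with fry and 9 on ranks, and 8 to 11 in the other fits on all arrays. The MYC and ribosome biogenesis list had an adjusted p of 0.10 after quantile normalisation again and 0.113 without the _x_at, _s_at and _a_at types, and the NF-kB list had 0.463 without those types and 0.0827 on ranks. Other lists newly passed: neutrophil granule and granulocyte genes without dim probe sets (0.0297), unfolded protein and heat shock genes with array weights (0.0414) and without CA replicate 3 (0.0187), apoptosis regulators without CA replicate 3 (0.0316) and with fry (0.0343), and with fry also the interferon (0.0172), hypoxia (0.00362) and TGF-beta, Notch and Wnt lists (0.00417).

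The replicate numbers were not treated as a pairing. Deviations from the group means correlated at 0.0413, 0.223 and 0.248 between same-numbered samples, and 5 of the 6 arrays correlated best with the array of their own number in the other group; the exception was CA replicate 1, which correlated best with DMSO replicate 2. This is a hint from the data of a link between equal numbers, which the labels do not state. The gap between dimmer and brighter genes followed the same order. In DMSO and CA it was -0.0372 and -0.0622 for replicate 2, 0.0517 and 0.0740 for replicate 3, and 0.0156 and -0.0565 for replicate 1. Whether this gap accounts for the correlations was not tested. With the number as a block, limma gave 6 genes (6 higher, 0 lower), all among the 177, and 1 probe set (1 higher, 0 lower), where 1218 genes and 2934 probe sets were lower without an adjustment, and 10 lists passed. Of the 177 genes, 167 were at least as bright as the median gene; whether low signal over background limited the calls among dimmer genes was not tested.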

Other observations

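The tests of receptor, homeobox and neighbouring genes, of short-lived transcripts, of the array floor, of the number of genes in other splits, of RNA degradation and of a weaker response were chosen only after the result was seen; those of array scaling, of dim probe set signal and of lists and probe sets in other splits were planned.

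Genes for G protein-coupled receptors were frequent among the risen genes. Defined by symbol, 11 of 270 measured receptor genes rose and 0 fell (limma), where a permutation test with 10000 random gene sets matched on expression had a median of 1 (one-sided p = 1e-04, the smallest these sets can give, adjusted p = 3e-04 over 3 such tests). Besides GPR183, S1PR3, GPR18, CCR2 and CCR7 they were the nucleotide receptor P2RY2 at 1.52-fold, the chemokine receptor CCR1 with a log2 change of 0.59, the succinate receptor SUCNR1 at 1.49-fold, GPRC5C at 1.38-fold, CXCR4 at 1.36-fold and ADGRL2 at 1.28-fold. Homeobox genes numbered 6 of 148 measured, with a random median of 1 (same permutation test, one-sided p = 2e-04, adjusted p = 3e-04): HMX2 at 1.65-fold, DLX2 at 1.61-fold, IRX5 at 1.53-fold, HLX at 1.53-fold, DLX5 with a log2 change of 0.59 and PBX3 at 1.29-fold. Second probe sets gave log2 changes of 0.07 for DLX2, -0.06 for ADGRL2, 0.14 for GPRC5C, -0.14 for S1PR3, 0.25 for CCR2 and 0.56 for CCR1. The other probe sets of CXCR4 gave 0.66 and 0.57. The random sets drew genes as if they were independent, so these p-values do not measure the spread between samples. GPR18 with GPR183 and CCR1 with CCR2 are neighbours, yet each gene was counted on its own. That CA raises the receptor and homeobox families is a hypothesis, since the families were defined on the data that tested them.

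Risen genes also lay beside one another. In the gene table of GRCh38.p14 the 166 risen genes held 8 neighbouring pairs, where matched random sets had a median of 1 and a 95th percentile of 4 (permutation test, one-sided p = 3e-04). The pairs were GPR18 with GPR183, TNF with LTB, CCR1 with CCR2, TEX2 with PECAM1, IL17RA with TMEM121B, and 3 pairs among 4 transcripts at the ANXA2R locus. Transcripts at that locus include an antisense one, CCR1 and CCR2 are similar in sequence, and the other probe set of LTB gave a log2 change of -0.011, so these pairs are uncertain. Without the ANXA2R locus there were 5 pairs (permutation test, one-sided p = 0.0210). Without CCR1 with CCR2 and TNF with LTB as well there were 3 (permutation test, one-sided p = 0.210). The pairs were taken out after the count was seen and from the risen genes only, while the random sets were left whole. The p-values of these reduced counts compare unlike sets, so they cannot decide the question. Since several pairs are uncertain, whether neighbours rose together more often than by chance stays open.

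The excess of rises over falls was weighed against array scaling and the floor of the array. After either of 2 rescalings at least 89.3% of the changed genes were higher, which argues against scaling differences left after RMA as the whole cause. The values were already quantile normalised by RMA, and rescaling cannot undo a shift that this step imposed, so that cause stays open. The excess was smaller with an intensity trend (82.4%), with the dim signal gap as a covariate (82.3%) and at an unadjusted limma p under 0.05 (1403 higher, 889 lower). Among the 167 changed genes at least as bright as the median gene 94.6% were higher, against 93.8% of all changed genes. This share cannot test for falls hidden at the floor, since it covers 167 of the 177 changed genes and no fall that went uncalled. Without dim probe sets, 88.6% of the changed genes were higher (311 higher, 40 lower). Of the 10 splits of the 6 arrays, 1 gave as many genes (177, at most 0 in the others by limma) and 1 as many probe sets (120, at most 0). At an unadjusted limma p under 0.05 the real split had 2292 genes and the others had 562 to 1998. The 10 splits are too few for a share under 0.05. In the other splits a response to CA would add to the spread within groups, so their 0 cannot be set against the 177 or the 120. A response to CA remains a hypothesis for the excess.

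The number of lists past the threshold was 10 in the real split, and 2 of the 10 splits gave as many; the highest of the others was 10, and the splits are too few for a share under 0.05. The other one set DMSO replicates 1 and 3 and CA replicate 3 against the rest, and these are the arrays on which dimmer genes read higher relative to brighter ones (gaps of 0.0156, 0.0517 and 0.0740, against -0.0372, -0.0565 and -0.0622). Whether this gap accounts for the lists of that split was not tested. This mixed split shared 5 of its lists with the real split. In camera the haematopoietic transcription factors and the immediate early list had adjusted p = 0.0196 in the mixed split. The MLL fusion target and sterol lists had 0.0234 there, and the G2/M list had 0.000374. For these 5 lists, passing camera at the preset correlation was therefore not particular to CA against DMSO. In camera 0 of the lists of the mixed split passed with an estimated correlation, against 2 in the real split besides the 4 recalled genes, which were listed for their response. A response to CA would add to the spread within the mixed groups and could raise the estimated correlation, so the 0 and the 2 cannot be set against each other. With the gap as a covariate, chosen after the mixed split was seen, 10 lists passed in the real split.

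CA replicate 3, which stood apart on the first principal component, was weighed against RNA degradation, dim signal and a weaker response. The log2 difference between 3' and 5' control probe sets of ACTB was 3.01 on this array and up to 3.28 on the others, which argues against degradation of its RNA. Quantile normalisation again lowered its gap to the nearest array from 0.678 to 0.534 of the range of all 6, so dim signal may account for part of it but not for the whole. On the 100 genes with the smallest p without this array, its change was 0.855 times that of the other two, where the same ratio was 0.990 and 1.01 for them; with a DMSO array held out as well, its ratio was 0.830, 0.726 and 0.867, the lowest of the CA arrays with each DMSO array held out, and those of the others were 0.864 to 1.07. A weaker response in this sample stays open, since 0.855 lies between the bounds set for and against it and 1 of the 3 held-out ratios lies below the lower bound. On the first component the array lay at 19.7, not between the DMSO arrays (-8.25 to 0.73) and the other CA arrays (-3.42 and -4.48). That argues against a weaker response alone as the cause of this gap. On the second component it lay at 1.70, between the DMSO arrays and the other CA arrays (8.69 and 13.0).

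The falls include HEXIM1, EGR1, SERTAD1 and PPP1R10. EGR1 is an immediate early gene with a short-lived transcript, so a general loss of short-lived transcripts was looked for. The immediate early and MAPK feedback list had a median log2 change of 0.08 (0.0752, bootstrap SE over genes 0.0350), with 30 of 44 members above 0. This list was thus not lower as a whole. Its members were not chosen by transcript lifetime, and HEXIM1, SERTAD1 and PPP1R10 are not among them. The list therefore cannot decide on a general loss of short-lived transcripts. At an unadjusted limma p under 0.05, 14 members were higher and 4 lower. The 4 were EGR1, ZFP36, JUNB and DUSP1, with log2 changes of -0.50, -0.15, -0.15 and -0.17, so a loss of some of these transcripts stays open.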
